A study of Mus musculus with 7 samples.

How the data were processed

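Gene expression was measured by RNA sequencing of whole kidneys from male mice. Per the labels, 3 libraries came from wild-type (WT) animals, replicates 1, 2 and 4, and 4 from animals carrying a double knockout (DKO) of Hs3st3a1 and Hs3st3b1, replicates 1 to 4. Each library has its own animal number in the labels, so each was treated as 1 animal and the replicate is the animal. Per the labels' protocols, tissue was lysed by sonication, total RNA was extracted with a column kit, and the libraries were made with a tagmentation kit that does not mark the strand and sequenced on an Illumina instrument. Genotype is the only factor that the labels name.

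The authors deposited a table of raw read counts per Ensembl gene, a second count table holding the genes they kept after a filter, and a table of CPM values (counts scaled to a common library size) adjusted by the trimmed mean of M-values (TMM). Per the submitters' processing notes the reads were aligned with STAR 2.5.2a, and edgeR, limma and DESeq2 were also used. The notes list GRCm38 (mm10) and also GRCh38, whose role they do not state. The read counter, the annotation release and the strand setting are not given in the sources used here. The deposited raw count table has 48733 rows, of which 48709 are Ensembl genes and 24 are transgene or spike-in sequences. These 24 rows held at most 0.000697% of the counts of any library and were left out of library sizes and tests. All 18797 rows of the filtered counts were identical to rows of the unfiltered ones, every dropped row had a largest count of at most 5, and every kept row had a largest count of at least 6. The deposited TMM-scaled signal table (CPM on the scale of the filtered counts) has 18866 rows, 69 of which repeat a gene, and it was used only for gene symbols. The CPM values given here were computed from the raw counts.

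Total counts ranged from 18330929 to 24259400 per library. Intervals on pooled reads are exact 95% binomial intervals, and a count of 0 was taken to allow 3 counts. Both cover counting error only, because they treat reads as independent and leave out variation between animals. The libraries also carry no molecular identifiers, so copies of the same molecule cannot be told from separate molecules. Chi-square statistics per gene between pairs of libraries were between 40.5 and 208, far above sampling noise, so no library was counted as a repeat of another.

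The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM scaling) of DKO against WT on raw counts. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 15394. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 with no minimum fold. Standard errors of log2 fold changes were derived from the F statistic. Both targeted genes were also tested by an exact two-sided permutation of CPM over the 35 splits of the 7 libraries, for which the smallest possible p is 0.0286. Values per group are mean ± SD of CPM.

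Lists of kidney cell types, heparan sulfate genes, signalling pathways, metabolism and RNA quality, 46 in all, were fixed before the data were examined. The 43 lists with at least 3 tested members were tested with camera (limma 3.58.1) on voom log2 CPM values at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Counts of members adjusted over the list alone use the edgeR p-values of that list. For each library, a list median is the median over members of the log2 CPM (prior count 2) minus the WT mean.

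Named genes followed a rule that was set at the same time as the lists. It took both targeted genes, up to 12 genes in each direction among those past the threshold, and from each list the members past the threshold, up to 4, or otherwise up to 2 members with the highest mean CPM, as values only. With fewer than 10 genes past the threshold it also took the 10 genes with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

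Gene positions, exon lengths (summed over merged exons) and GC content came from GENCODE M21 on GRCm38, which matched 48349 of the 48709 Ensembl rows. Sequence shared between a pair of genes was searched with blastn 2.17.0. The tests were checked on counts simulated from these libraries' means, sizes and dispersions for the DKO against WT comparison. Of the 15394 genes simulated, 200 were changed. At an adjusted p under 0.05 edgeR recovered 2% of the 50 genes changed 1.5-fold, 40% of those changed 2-fold, 78% of those changed 4-fold and 96% of those changed 8-fold, with 10 false calls among 118. DESeq2 1.42.0 recovered 12%, 54%, 90% and 90% at those sizes, with 34 false calls among 157. Of 20 simulated lists of 20 genes, camera called all 10 that were shifted 1.5-fold and 0 of the 10 that were not. Genes were drawn independently in these simulations. The checks therefore do not cover correlation between genes, and do not give camera's rate of false calls on real lists.

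The alternatives tried were DESeq2, limma-voom, other size factors, other low-count filters, a fit without robust dispersion, each library left out in turn, the replicate number or the animal-number range as a block, and other thresholds. Alternatives chosen after the data were seen removed a length and GC trend, weighted samples by quality, ran DESeq2 without WT replicate 4, and ran the lists without WT replicate 4 and DKO replicate 3.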

Results

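Kidney RNA from 3 WT and 4 DKO male mice was sequenced to compare gene expression with and without Hs3st3a1 and Hs3st3b1, a pair of enzymes that add sulfate at the 3-O position of glucosamine in heparan sulfate. According to its title, the study concerns kidney and glomerular size and glomerular architecture after loss of both enzymes. The WT libraries held 19114393, 19336543 and 22610701 counts (replicates 1, 2 and 4). The DKO libraries held 23144061, 18330929, 18640040 and 24259400 (replicates 1 to 4). The 10 most abundant genes took between 11.8% and 13.9% of the gene counts of a library.

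Transcripts of Hs3st3a1 were nearly absent from DKO kidneys, whereas reads assigned to Hs3st3b1 persisted. Hs3st3a1 (ENSMUSG00000047759, chromosome 11, positions 64435332 to 64522841 on GRCm38, plus strand) has 2 merged exons. It received 29, 13 and 12 reads in WT replicates 1, 2 and 4, and 1, 0, 0 and 3 reads in DKO replicates 1 to 4. This was 0.920 ± 0.510 CPM in WT (SD, n = 3) and 0.0416 ± 0.0577 CPM in DKO (SD, n = 4). A count of 0 allowed up to 0.158 CPM in DKO replicate 2 and 0.154 CPM in DKO replicate 3. Pooled over libraries, the DKO to WT ratio was 0.0512 (95% interval 0.0135 to 0.139, 4 against 54 reads). Every DKO library lay below every WT library, with an exact permutation p of 0.0286, the smallest that the 35 splits can give. The edgeR quasi-likelihood log2 fold change was -4.15 (SE 0.77), with a Benjamini-Hochberg adjusted p of 0.163 over all genes and 4.14e-04 adjusted over the list alone, here both targeted genes.

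Hs3st3b1 (ENSMUSG00000070407, chromosome 11, positions 63885792 to 63922290, minus strand, 2 merged exons) received 56, 90 and 112 reads in WT and 33, 106, 65 and 108 reads in DKO. Its level was 4.32 ± 1.26 CPM in WT (SD, n = 3) and 3.69 ± 1.75 CPM in DKO (SD, n = 4). The difference was smaller than the spread between animals (log2 fold change -0.23, SE 0.39, edgeR adjusted p 0.755, exact permutation p 0.657) and turned to 0.035 without DKO replicate 1. The counts cover the whole gene and the deleted part is not given in the sources used here, so the Hs3st3b1 count does not check the label. The row for a neomycin resistance cassette (Neo) received 0 reads in each WT library and 73, 75, 81 and 125 reads in DKO replicates 1 to 4. Both Hs3st3a1 and Neo therefore separated the 7 libraries as their labels do.

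**Figure D1:**
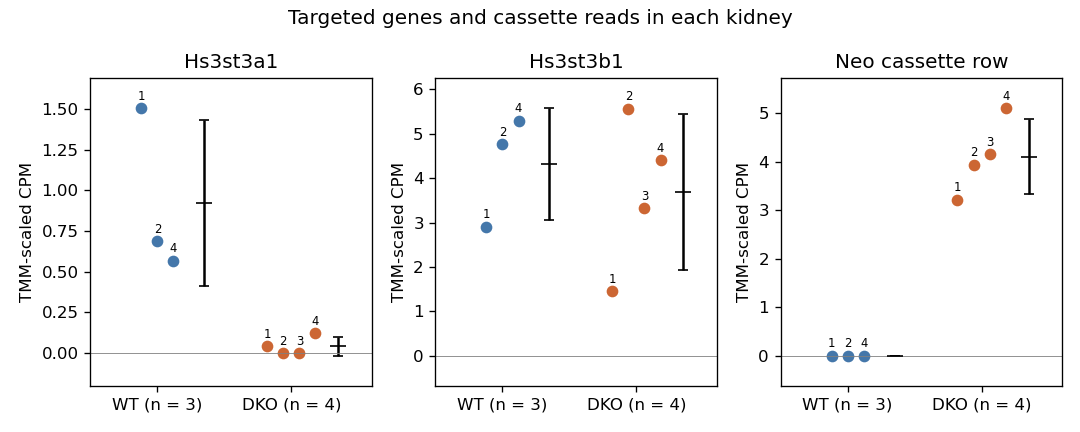
Levels of Hs3st3a1, Hs3st3b1 and the Neo cassette row in each kidney, as TMM-scaled CPM on a linear axis with a line at 0. Numbered points are replicates (3 WT in blue, 4 DKO in orange), and bars show the mean ± SD; Hs3st3a1 was measured at 0 to 0.122 CPM in DKO, where a count of 0 allows up to 0.158 CPM, Hs3st3b1 overlapped between groups, and Neo was found in the 4 DKO libraries and at 0 in the WT libraries.

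Across the transcriptome, the 10 genes with the smallest p between DKO and WT kidneys had varied known functions, and whether they passed adjustment over all genes depended on the tool and the low-count filter. Pck1, the enzyme that commits carbon to gluconeogenesis, was at 380 ± 10.5 CPM in WT (SD, n = 3) and 798 ± 108 CPM in DKO (SD, n = 4), a 2.10-fold difference (log2 fold change 1.07, SE 0.17). Nedd4l, a ubiquitin ligase that acts on the epithelial sodium channel, was at 30.1 ± 2.91 CPM in WT and 54.0 ± 5.03 CPM in DKO (log2 fold change 0.84, SE 0.15). Ssh2, a cofilin phosphatase, Cplane1, a ciliogenesis factor, and the dynamin Dnm3 had log2 fold changes of 1.30, 1.32 and 1.35. These genes and Nedd4l are long, with 13095 to 24452 nt of exons. Among all genes with at least 7130 nt, 78.1% were higher in DKO, so their direction is shared by most long genes. Lars2, given below, has 11089 nt and was lower. Hsf2bp, which acts in meiotic recombination, had a log2 fold change of -1.24 and the noncoding Gm17225 one of -1.86. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 2839 ± 783 CPM in WT and 1087 ± 248 CPM in DKO (log2 fold change -1.38, SE 0.25). The noncoding Gm15564 had the same fold change, and its transcript shares 72 nt at 98.6% identity with Lars2. The ratio of their counts was between 2.92 and 3.07 in every library, although the genes lie on chromosomes 9 and 16. Both rows may therefore count reads of 1 shared origin, and these counts do not show that Lars2 itself was lower. The source of such reads was not tested. With Hs3st3a1, these are the 10 genes with the smallest p, each at an edgeR adjusted p of 0.163, and in each of them every DKO library lay on the same side of every WT library. DESeq2 called 8 of the 10, with adjusted p from 7.63e-07 for Pck1 to 6.19e-04 for Dnm3, and gave no adjusted p for Gm17225 and Hs3st3a1. With no low-count filter edgeR called all 10, with adjusted p from 0.00129 to 0.0366. DESeq2 also called some of the other genes named here or among the additional observations, with adjusted p from 0.00669 to 0.0487. They were Cyp2d22, Odc1, Cldn16, Papss2, Slc34a1, Podxl, Rhbg, Znrf3, Myh11, Fzd4, Slc35b2 and Cox4i1. Cldn16 was also called by edgeR with no low-count filter (adjusted p 0.0482, in a range of 0.0218 to 0.494 over the alternatives).

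No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, while 3250 of 15394 genes (21.1%) had an unadjusted p under 0.05, 1518 higher and 1732 lower in DKO. DKO and WT libraries did not overlap for 2675 genes (17.4%, where chance gives 5.71% as an average over all splits of the libraries). Genes vary together, so any single split can lie far from that average. The share was not computed for other splits. DESeq2 called 672 genes on the same counts, 222 higher and 450 lower, and 10 without WT replicate 4, and limma-voom called 0. The edgeR count at an unadjusted p under 0.05 was 1582 without WT replicate 4 and 2075 without DKO replicate 2. Without WT replicate 2 edgeR called 1 gene, Cyp2d22, a cytochrome P450 named after its value was seen (log2 fold change 2.14, adjusted p 0.00806), and without DKO replicate 1 it called 7 genes, all higher in DKO, Dnm3 among them (adjusted p 0.04996).

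Among the gene groups, camera with its preset correlation called ribosomal protein, respiratory chain and T and natural killer (NK) cell genes as lower and fatty acid oxidation genes as higher in DKO kidneys. With an estimated correlation none of these 4 lists was called (adjusted p 0.887 each). With a length and GC trend removed all 4 were called, with medians of -0.39 for the ribosomal protein, -0.36 for the respiratory chain, -0.59 for the T and NK cell and 0.48 for the fatty acid list. Of 32 cytoplasmic ribosomal protein genes 31 were lower in DKO (median log2 fold change -0.51, camera adjusted p 5.59e-10, and 0.887 with an estimated correlation). No member passed over all genes and 13 passed adjusted over the list alone. The 2 most abundant members were Rpl3, at 537 ± 25.7 CPM in WT and 517 ± 49.6 CPM in DKO, and Rps3, at 454 ± 222 CPM and 253 ± 59.5 CPM. Ribosomal protein genes have many processed pseudogenes, so reads can be divided between copies. Of 25 nuclear genes of oxidative phosphorylation 23 were lower (median -0.56, camera adjusted p 1.44e-06, and 0.887 with an estimated correlation), with 10 members passing adjusted over the list alone. Cox4i1, a subunit of cytochrome c oxidase, was at 3087 ± 733 CPM in WT and 1989 ± 370 CPM in DKO. Atp5f1b, the catalytic subunit of the ATP synthase, was at 2765 ± 489 CPM and 2474 ± 269 CPM. Mitochondrially encoded transcripts had a median of -0.0048 over the 7 tested of 13 listed genes (camera adjusted p 0.818). They were called as higher once a length and GC trend was removed (median 0.42, camera adjusted p 0.0151). Genes of the mitochondrial genome took only 0.88% to 1.37% of the gene counts of a library.

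Of 22 genes of fatty acid oxidation and PPAR targets 20 were higher in DKO (median 0.47, camera adjusted p 0.0016, and 0.887 with an estimated correlation), with 0 members passing adjusted over the list alone. Acadm, the medium-chain acyl-CoA dehydrogenase, was at 1308 ± 646 CPM in WT and 1392 ± 303 CPM in DKO. The call was lost without DKO replicate 1 (camera adjusted p 0.0773, in a range of 6.03e-06 to 0.887 over the alternatives).

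Of 9 T and NK cell markers 8 were lower in DKO (median -0.97, camera adjusted p 0.0244, and 0.887 with an estimated correlation). The 4 members that passed adjusted over the list alone, chosen after their values were seen, were the T cell receptor components Cd3g and Cd3d, the activating receptor Klrk1 and the granule protein Nkg7, with log2 fold changes of -1.41, -1.68, -2.06 and -0.97. All 4 were scarce, between 1.85 and 3.85 CPM on average in WT. The most abundant members were Ptprc, at 7.76 ± 2.46 CPM in WT and 6.51 ± 1.75 CPM in DKO, and Trac, at 5.02 ± 0.732 CPM and 5.60 ± 1.02 CPM. The list median of WT replicate 2 (-0.77) lay within the DKO range (-0.92 to -0.69). In that library the red-cell genes of the erythroid list were also lowest, at -1.61 against 0.54 and 0.74 in WT replicates 1 and 4. The T and NK call was lost without WT replicate 1, WT replicate 4, DKO replicate 1 or DKO replicate 3 (camera adjusted p 0.199, 0.0561, 0.0578 and 0.051, in a range of 1.65e-04 to 0.887 over the alternatives). The list median in these voom fits was -0.74, -0.54, -0.76 and -0.78, against -0.87 in the voom fit of all libraries.

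All 4 list calls used camera's preset correlation. With fry, which asks whether a list's genes move on balance one way, their adjusted p was between 0.458 and 0.522. Values of the libraries overlapped between groups in each of the 4 lists except oxidative phosphorylation, where the DKO medians lay between -0.76 and -0.28 and the WT medians between -0.20 and 0.36.

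**Figure D2:**
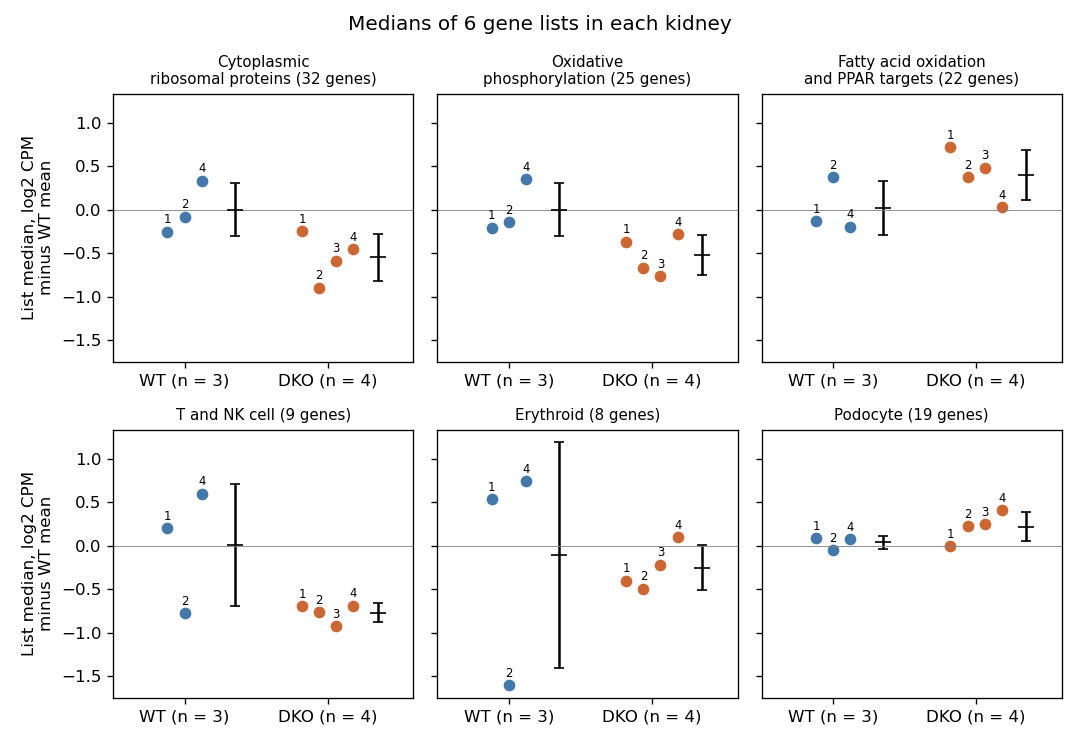
Median log2 CPM of 6 gene lists in each library, relative to the mean of the WT libraries for each gene. Numbered points are replicates (3 WT in blue, 4 DKO in orange) and bars show the mean ± SD; the ribosomal protein and oxidative phosphorylation lists averaged -0.55 and -0.52 in DKO, the fatty acid list 0.40, and WT replicate 2 lay apart from the other WT libraries for T and NK cell and erythroid genes.

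For the glomerulus, the structure named in the study's title, podocyte and slit diaphragm genes were slightly higher in DKO without passing the test. Of 19 genes 14 were higher (median 0.23, camera adjusted p 0.0754), and the list was called without WT replicate 4 (0.0339) and without DKO replicate 1 (0.0421), in a range of 0.0264 to 0.887 over the alternatives. Its members are long (median exon length 6620 nt), and with a length and GC trend removed the median was 0.071 (adjusted p 0.272). Its most abundant members were Actn4, an actin crosslinker, at 919 ± 179 CPM in WT and 1170 ± 185 CPM in DKO, and Tcf21, a transcription factor, at 77.9 ± 31.9 CPM and 44.9 ± 14.8 CPM. At an unadjusted edgeR p under 0.05, 3 members were higher and 1, Tcf21, was lower, and 0 passed adjusted over the list alone. Podxl, among those 3 and named after its value was seen, was called by DESeq2 (log2 fold change 0.51, adjusted p 0.0294). Glomerular basement membrane genes were higher in 8 of 12 (median 0.23, adjusted p 0.373, with the test's direction reversed once a length and GC trend was removed). In that list Npnt was at 97.54 ± 3.98 CPM in WT and 87.4 ± 14.1 CPM in DKO, and Col4a3, a chain of type IV collagen, varied so widely between animals of both groups (20.4 to 9468 CPM) that its group means were not informative. Glomerular endothelium (7 of 9 higher, median 0.21, adjusted p 0.463), mesangium (6 of 10, 0.013, 0.56) and parietal epithelium (7 of 9, 0.24, 0.485) were not called.

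Among tubular cell types, markers of the first proximal tubule segments were higher in 9 of 12 genes (median 0.23, camera adjusted p 0.069). Slc34a1, the sodium phosphate cotransporter, was at 3201 ± 191 CPM in WT and 4555 ± 362 CPM in DKO, and Gatm, an enzyme of creatine synthesis, at 3925 ± 423 CPM and 3119 ± 793 CPM. That list was called without WT replicate 2 or WT replicate 4, with quality weights and with no low-count filter. Loop of Henle markers were lower in 9 of 12 genes (median -0.35, adjusted p 0.0953), and this list was called without WT replicate 2 or DKO replicate 4 and with no low-count filter. Umod, which encodes uromodulin, was at 6419 ± 1649 CPM in WT and 3996 ± 995 CPM in DKO, and the potassium channel Kcnj1 at 872 ± 212 CPM and 600.1 ± 93.6 CPM. Cldn16, a tight junction protein that was the only member to pass adjusted over the list alone and was named after its value was seen, had a log2 fold change of -0.89 (SE 0.22). The ammonia transporter Rhbg (-0.66), also chosen after its value was seen, was the only one among 14 intercalated cell markers to pass in that way. Markers of the last proximal segment, the distal convoluted tubule, the principal cell and the intercalated cell were not called (adjusted p 0.676, 0.359, 0.947 and 0.359).

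Genes of heparan sulfate synthesis and editing other than the targets were higher in 14 of 21 (median 0.23, camera adjusted p 0.421, and 0.022 for the median with a length and GC trend removed), with 0 passing adjusted over the list alone. The most abundant were the enzymes that make the sulfate donor. Papss2 was at 78.9 ± 37.7 CPM in WT and 162 ± 23.1 CPM in DKO (log2 fold change 1.04, SE 0.28, edgeR adjusted p 0.163, DESeq2 adjusted p 0.0227, in a range of 0.0227 to 0.494 over the alternatives), and Papss1 at 80.3 ± 14.3 CPM and 68.7 ± 8.43 CPM. Slc35b2, on the same list and named after its value was seen, was called by DESeq2 in the other direction (log2 fold change -0.72, adjusted p 0.0387). Of the other 3-O-sulfotransferases, Hs3st1 was at 1.37 ± 0.663 CPM in WT and 1.47 ± 0.344 CPM in DKO, and Hs3st6 at 1.18 ± 0.130 CPM and 1.28 ± 0.310 CPM. These differences were smaller than the spread between animals. Proteoglycan core proteins had a median of -0.01 over 15 genes (adjusted p 0.655, with a mean of 0.10). Signalling lists for FGF (median 0.15), WNT (0.11), TGF-beta and BMP (0.16) and VEGF and angiopoietin (0.18) had camera adjusted p values of 0.328, 0.373, 0.439 and 0.813. In the WNT list the most abundant members were the receptor Lgr4, at 1255 ± 218 CPM in WT and 1088 ± 631 CPM in DKO, and the ubiquitin ligase Znrf3, at 236 ± 34.8 CPM and 385 ± 83.0 CPM. Znrf3 (log2 fold change 0.71) and the receptor Fzd4 (0.52), the latter named after its value was seen, passed adjusted over the list alone.

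Lists linked to sex hormones, B cells, macrophages, the interferon response and injury did not pass the camera test. Genes with higher expression in female kidneys were higher in 9 of 11 (median 1.11, camera adjusted p 0.0506). Of these, Acsm2 was at 1576 ± 220 CPM in WT and 1273 ± 429 CPM in DKO, and Cyp4a14, a fatty acid hydroxylase also on the fatty acid list, at 91.5 ± 112 CPM and 645 ± 574 CPM. Androgen-responsive genes were lower in 10 of 15 (median -0.14, adjusted p 0.178). Cyp4b1 was at 3750 ± 1062 CPM and 3512 ± 1381 CPM, Kap, the androgen-regulated kidney protein, at 3452 ± 1711 CPM and 1030 ± 736 CPM, and Odc1, the first enzyme of polyamine synthesis and the only member to pass adjusted over the list alone (named after its value was seen), at 69.2 ± 25.5 CPM and 31.1 ± 8.73 CPM. B and plasma cell genes were lower in 7 of 8 (median -0.74, adjusted p 0.0506), with Ighm at 24.1 ± 9.37 CPM in WT and 15.9 ± 5.10 CPM in DKO and Igkc at 18.3 ± 11.2 CPM and 9.83 ± 7.50 CPM. Macrophage genes (10 of 12 lower, median -0.36, adjusted p 0.0523) and interferon response genes (13 of 15 lower, median -0.27, adjusted p 0.0506) were close to the threshold. Among the macrophage genes, Lyz2, a lysozyme, was at 132 ± 61.2 CPM in WT and 65.7 ± 29.8 CPM in DKO, and Cd74, the invariant chain, at 400.0 ± 123 CPM and 370.0 ± 72.0 CPM. The B and plasma cell, macrophage and female-biased lists were called without WT replicate 2, DKO replicate 2 or DKO replicate 4, the interferon list without any 1 of these or DKO replicate 3, and the androgen list without WT replicate 4 or DKO replicate 4. The B and plasma cell, interferon and female-biased lists were also called with the authors' genes, with the animal-number range as a block and with no low-count filter, the macrophage list with no low-count filter and with quality weights, and the female-biased list with a length and GC trend removed (median 0.95, camera adjusted p 0.0129). Injury markers were higher in 11 of 16 (median 0.29, adjusted p 0.56).

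Genes with a large summed exon length were higher and genes with a small one lower in DKO, in steps that ran through the whole transcriptome. The median log2 fold change went from -0.31 in the shortest of 5 equal classes of genes (57 to 2021 nt of exons) through -0.09, 0.04 and 0.14 to 0.26 in the longest (7130 to 123179 nt). Across 15369 genes, which are not independent replicates, the Spearman correlation of fold change with exon length was 0.40 and that with GC content 0.0068. Per library, the correlation of centred log2 CPM with exon length was -0.20, -0.25 and -0.33 in WT and -0.08, 0.38, 0.27 and 0.22 in DKO replicates 1 to 4. The group means were -0.26 ± 0.06 (SD, n = 3) and 0.20 ± 0.20 (SD, n = 4), with an exact permutation p of 0.0571. Ribosomal protein and oxidative phosphorylation genes are short (median exon length 1918.5 and 2101 nt, against 4008 nt for all tested genes), so both lists moved with this trend.

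**Figure D3:**
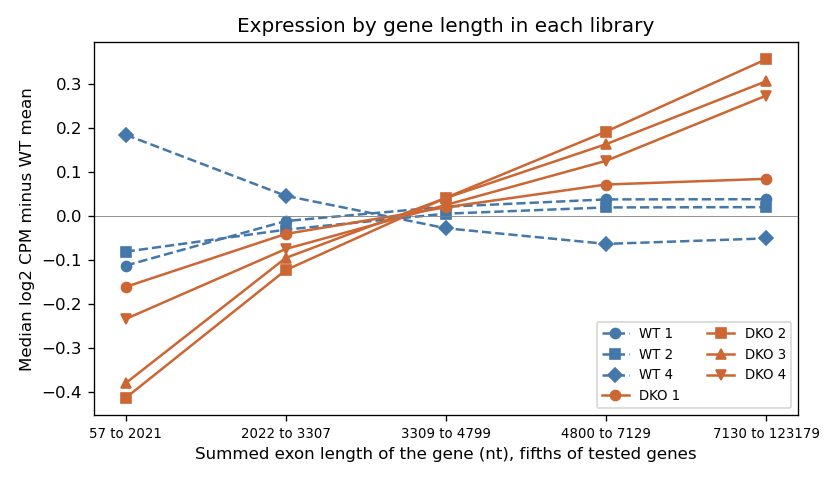
Median log2 CPM relative to the WT mean in 5 classes of exon length, 1 line per library (WT dashed in blue, DKO solid in orange). In the longest class DKO replicates 2, 3 and 4 lay between 0.27 and 0.36, DKO replicate 1 at 0.08 and the WT libraries between -0.05 and 0.04.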

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

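The length-matched lists, the list tests without single libraries and most tests on other splits were set out before their outcomes were seen, but the patterns they address had been seen, and the split test on edgeR's adjusted count was chosen after that count was known.

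Of 116 values tested for a DKO library far from the other 3, 9 had one, where chance flags about 1 in 20, or 5.80. In DKO replicate 1, Nedd4l was at 46.6 CPM against 55.6 to 57.3 CPM in the others, and the median of the interferon response list was -0.60 against -0.13 to -0.04 (log2 CPM relative to the WT mean). In DKO replicate 3, Ptprc, the common leukocyte antigen, was at 3.90 CPM against 7.13 to 7.51 CPM, and Znrf3 at 508 CPM against 329 to 360 CPM. In DKO replicate 4, Lgr4 was at 2027 CPM against 677 to 863 CPM, and the list medians were 0.18 for cholesterol synthesis (others -0.29 to -0.24), 0.49 for the distal convoluted tubule (0.01 to 0.05) and 0.19 for mitochondrially encoded genes (-0.04 to -0.03). That library also held the most Neo reads, 125 against 73 to 81. Neo was tested on raw counts, and DKO replicate 4 was the deepest library (24259400 counts), so this flag, which is among the 9, does not allow for depth. Scaled for depth, Neo was at 5.10 CPM there and at 3.21 to 4.15 CPM in the other DKO libraries.

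Outside the genes, 3 marker sequences had reads in DKO above the WT level. Neo had 354 reads in the 4 DKO libraries and 0 in the 3 WT libraries, at least 81.6-fold higher in CPM than a pooled floor of 3 counts. LacZ had 90 reads in DKO and 8 in WT. DsRed had 15 in DKO, with 0 in DKO replicate 2, and 0 in WT (exact permutation p 0.143). The beta-lactamase sequence went the other way, with 11 reads in WT and 2 in DKO (exact permutation p 0.0571). How the alleles were built is not given in the sources used here, and no explanation was tested.

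The lower ribosomal protein and oxidative phosphorylation lists, the higher fatty acid oxidation list and the lower T and NK cell list were weighed against exon length. This length is summed over merged exons and can exceed that of a transcript. Among 10000 random lists matched on it and on expression, their medians lay at percentiles 0.16, 0.07, 100 and 0.01. Matched lists had medians of -0.28 and -0.25 for the first pair. The random lists drew genes independently, so a list whose genes vary together can lie outside them whatever the role of length. These percentiles therefore do not decide whether length is the whole cause. Without WT replicate 4 the ribosomal protein and oxidative phosphorylation lists had camera adjusted p values of 1.43e-08 and 9.42e-06, and without DKO replicate 3 the fatty acid list had 0.00156. At camera's preset correlation those single libraries did not alone carry these calls. WT replicate 4 did stand apart, with list medians of 0.34 (ribosomal protein) and 0.36 (oxidative phosphorylation). WT replicates 1 and 2 were at -0.25 and -0.08, and at -0.20 and -0.14. Without DKO replicate 1 the fatty acid list was not called (0.0773), and the T and NK list was not called without WT replicate 1 (0.199), WT replicate 4 (0.0561), DKO replicate 1 (0.0578) or DKO replicate 3 (0.051). In those 4 fits the median of the T and NK list stayed between -0.78 and -0.54. Chance could not be excluded for the number of lists, since 32 of the 35 splits called at least the 4 of the real split and the highest other called 20, so a genotype effect and sample structure unrelated to genotype both stay open.

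For the gene counts chance could not be excluded either. The real split gave 3250 genes at an unadjusted p under 0.05 in edgeR and 672 calls in DESeq2, 2 of the 35 splits gave as many in each case, and the highest other split gave 3611 and 1220. For edgeR's adjusted calls all 35 splits gave at least the real 0, which the count itself fixes, and the highest other gave 73. The highest other was in each case the split that sets DKO replicates 2, 3 and 4 against DKO replicate 1 and the WT libraries, which points to a structure of the samples. That split matches genotype in 6 of the 7 libraries, so a genotype effect that is weak in DKO replicate 1 and a structure unrelated to genotype both stay open.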

How the results depend on the processing

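The alternatives that removed a length and GC trend, weighted samples by quality, ran DESeq2 without WT replicate 4, or left out WT replicate 4 and DKO replicate 3 together were chosen after seeing the data. The cause was not tested for any change given here, unless stated.

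The number of genes called (0 in edgeR, with 3250 at an unadjusted p under 0.05) was 672 with DESeq2, 66 with no low-count filter, and 10 with DESeq2 without WT replicate 4, where 1547 had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 7 calls and 1582 to 3796 genes at an unadjusted p under 0.05. Hs3st3a1 kept its direction under every alternative run. Among those that gave it an adjusted p, which excludes DESeq2, it passed with no low-count filter alone (log2 fold change -4.15, edgeR adjusted p 0.0104, in a range of 0.0104 to 0.494).

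The number of lists called (4) was 11 with no low-count filter, 7 with the authors' genes, 7 with the animal-number range as a block, 7 with quality weights, 0 with an estimated correlation, 0 with fry's test of movement one way, and 3 to 12 with 1 library left out. With the length and GC trend removed, camera's direction turned for 6 lists. Glomerular basement membrane (adjusted p 0.612, in a range of 0.116 to 0.887), glomerular endothelium (0.915), VEGF and angiopoietin (0.915) and proteoglycan cores (0.915) turned to lower, and urothelium (0.593) and mitochondrially encoded genes (0.0151, called) turned to higher.

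With the replicate number as a block, 7 lists (the 4 and the B and plasma cell, interferon and female-biased lists) and 0 genes were called, with 2346 genes at an unadjusted p under 0.05, and Cyp4b1 and Cd74 turned to 0.078 and 0.054. Deviations of same-numbered libraries correlated at -0.13, 0.16 and 0.14. Of the WT libraries only replicate 2 correlated best with the DKO library of its number, which is a hint from the data at most. So few pairs cannot decide whether same-numbered libraries share more than a number, so pairing stays open.

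Log2 fold changes of some genes that were not called also turned. With 1 library left out, the ranges were -0.49 to 0.035 for Hs3st3b1, -0.16 to 0.56 for Acadm, -0.26 to 0.41 for Hs3st1, -0.021 to 0.24 for Hs3st6, -0.38 to 0.15 for Cyp4b1, -0.30 to 0.14 for Cd74, -1.01 to 0.077 for Zfp868, -0.011 to 3.51 for Ptp4a2 and -0.28 to 3.72 for Gm13422. Acadm was at -0.17 with DESeq2 without WT replicate 4, and with the length and GC trend removed Cyp4b1 was at 9.62e-05 and Cd74 at 0.046.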

Other observations

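The tests on genes with discontinuous levels and on the chromosome 11 region were chosen after those genes were seen.

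Circadian clock genes were higher in DKO in 13 of 16 (median 0.52, camera adjusted p 0.125, and called without DKO replicate 4 or with no low-count filter), with the list median of DKO replicate 3 at 1.65 and those of the other DKO libraries between -0.09 and 0.46. Per3, a clock repressor, was at 687 CPM in DKO replicate 3 and between 76.4 and 248 CPM in the other DKO libraries, and Tef, a clock output factor, was at 296 CPM against 77.8 to 138 CPM. Smooth muscle and urothelium were not called (camera adjusted p 0.51 and 0.655), and urothelium had a median of 0.012 but a mean of -0.18, with camera's direction lower. By fry's test for changes in either direction, smooth muscle (adjusted p 0.00131), the first proximal tubule segments (0.028) and the loop of Henle (0.0452) passed. The myosin Myh11 in the smooth muscle list (log2 fold change 0.75) and the keratin Krt15 in the urothelium list (-1.13) passed adjusted over the list alone and were named after their values were seen.

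The rise of log2 fold change with exon length was weighed against more unspliced RNA in DKO, which would favour genes with long introns. With exon length and expression held fixed, the partial Spearman correlation of fold change with gene span was 0.0811 across genes, between the bounds set beforehand, so unspliced RNA and other sources cannot be told apart with these counts. The partial correlation with exon length at fixed span was 0.301. Processed pseudogenes had a median of -0.34 over 563 genes, and genes of unverified models (TEC) one of 0.63 over 207. A genotype effect was not separated from differences in RNA handling between animals.

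For 12 genes the libraries fell into levels at least 8-fold apart, and for 0 of them did the widest gap divide the libraries by genotype. Slco1a1 and Gm6300 were still lower in every DKO library than in every WT library. Slco1a1 was at 160 to 182 CPM in WT and 1.23 to 117 CPM in DKO, and Gm6300 at 13.8 to 19.6 CPM and 0 to 9.39 CPM. Col4a3 was at 20.6 and 20.4 CPM in WT replicate 1 and DKO replicate 1 and between 1491 and 9468 CPM elsewhere. Mal2 was at 1110 CPM in WT replicate 4 and between 26.1 and 44.9 CPM elsewhere. Zfp868 and Med1 were at most 15.02 and 28.6 CPM in DKO replicates 2 and 3, and at least 222 and 305 CPM elsewhere, and Ptp4a2 and Gm13422 were high in WT replicate 2, DKO replicate 2 and DKO replicate 4. The genes named in this paragraph were chosen after their values were seen. The 12 genes divided the libraries in 8 ways, which argues against 1 technical batch, and alleles segregating among the animals may be a source but were not tested.

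Genes near both targets could differ because strain sequence was carried along with the targeted alleles. Within 10 Mb of both genes on chromosome 11, 22.0% of 268 genes had an unadjusted edgeR p under 0.05, against 21.1% of all tested genes and a 95th percentile of 27.9% over 933 windows elsewhere. This argues against a raised share in that region, and the list of chromosome 11 neighbours had a camera adjusted p of 0.818. A share cannot show whether single genes were affected. Ssh2, among the 10 genes with the smallest p, lies on chromosome 11 beyond the region, starting at 77216287 where the region ends at 74522841. Linkage of Ssh2 to the targeted alleles was not tested.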
